A study of Homo sapiens with 6 samples.

How the data were processed

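RNA was measured by sequencing of human umbilical vein endothelial cells (HUVECs, primary cells from the lining of a vein) after transfection of gapmers, short antisense oligonucleotides that direct cleavage of a matching RNA. The labels list 6 samples, 3 named control and 3 named knockdown of the long non-coding RNA SNHG12. Per the labels' protocols, cells at passages 2 to 3 received 25 nM gapmer, ribosomal RNA was depleted before library construction, and 250 µM hydrogen peroxide was applied for 4 hours. That protocol is written for every sample, while the labels' culture field calls the controls untreated and the knockdowns treated with peroxide. Whether peroxide differed between the groups is therefore open, and any difference between them carries this doubt.

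The deposited values are a signal: gene counts divided by a size factor of each library, as the authors normalized them. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and DESeq2 were used with GRCh38. The strand setting and the counting tool are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The table holds 15906 genes, each with at least 61 reads summed over the 6 columns. Of the gene identifiers, 15782 were found in the gene name table and 15854 in GENCODE release 29, from which coordinates, GC content and gene length were taken.

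Columns were matched to samples by the sample numbers in their headings alone. The number 6, that of knockdown 3, heads 2 columns, and the number 3, that of control 3, heads 0. The mean of the 2 columns headed 6 was used as knockdown 3 and counted once, and control 3 was not analysed here. In the table the headings run 1, 5, 2, 6, 4 and 6, and this order was not used to assign samples. The comparison is thus 2 controls against 3 knockdowns, where 3 against 3 had been planned. The 2 columns differ by more than sampling noise (chi-square per gene 5.13, where counting noise alone gives about 1), and the second is closer to knockdown 2 (4.73) than to the first, so they appear to be different libraries, and 1 of them may belong to another sample. Nothing in the labels says that replicates came from separate cultures or donors, so p-values measure only the spread between these samples.

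Whole reads could be recovered from the deposited values: 100% of values in each column were whole multiples of 1 read within 0.01 read. Recovered totals ran from 25168013 to 35768953 reads per column. Reads of the 2 columns headed 6 were added for count models.

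Deposited values were transformed as log2(value + 1), which understates changes of genes with low values. Genes with a value of at least 10 in at least 3 samples were tested (15656 genes) with limma 3.58.1 (trend and robust settings, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3, with group as the single term. Beside it, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 were run on the recovered reads. SNHG12 was also compared by an exact two-sided permutation test. Lists of genes were tested with camera from limma at a preset correlation of 0.01, adjusted over the 39 of 43 lists with at least 3 measured members, and again with an estimated correlation and with fry.

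The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names SNHG12, up to 12 genes per direction with the largest change among those past the threshold, and up to 4 members of each list with the smallest unadjusted p. Some genes the rule takes are not reported here. Where fewer than 5 genes pass in a direction, it names the 5 with the smallest unadjusted p and a mean of at least 50. From the same rule applied without knockdown 1, a small number of genes are named as well, and these were chosen after their values were seen.

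The procedure was tested on simulated counts with 200 changed genes, drawn from the real means and depths at a dispersion of 0.01. With all 3 knockdowns changed, limma on 5 samples recovered 100% of genes changed by 1 on the log2 scale (15666 genes tested). With only 2 of the 3 changed, limma recovered 0% of them (15647 genes tested), and 98% once the unchanged library was left out (15455 genes tested). These simulated shares describe this design and not the real libraries.

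Alternatives were other pseudocounts, filters and scalings, array weights, a replicate block, count models and leaving out each sample. Alternatives added after the data were seen were each column headed 6 alone, a loess correction for GC content (span 0.5), leaving out control 1 together with knockdown 1, and combinations of these with knockdown 1 left out. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for tables and figures.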

Results

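Expression of 15906 genes was measured in HUVECs labelled as control or as knockdown of SNHG12, a long non-coding RNA that hosts small nucleolar RNAs. Of the 6 samples in the labels, 2 controls and 3 knockdowns were compared. Recovered depth was 25424726 reads in control 1, 32521208 in control 2, 35768953 in knockdown 1 and 30998022 in knockdown 2. The 2 columns averaged as knockdown 3 held 25168013 and 31277938 reads. The comparison asks which transcripts differ after a gapmer against SNHG12, with the doubt over peroxide that the labels leave.

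SNHG12 itself was not lower in any library labelled knockdown. SNHG12 (ENSG00000197989) lies on the minus strand of chromosome 1 from 28578538 to 28583132 in GRCh38, annotated as an antisense non-coding gene. With the exons of all its annotated transcripts merged, 9.54% of its 4266 exonic bases are also exonic in another gene. Its normalized count was 406 in the library labelled control 1 and 411 in that labelled control 2. It was 452 in the library labelled knockdown 1, 738 in knockdown 2, and 681 and 759 in the columns of knockdown 3. The means were 408 ± 3.66 (SD, n = 2) and 637 ± 160 (SD, n = 3), a log2 difference of 0.61 ± 0.23 (SE) with an adjusted p of 0.519 by limma. The exact two-sided permutation test gave p = 0.2, the smallest that its 10 splits allow. The direction goes against the labels, so "the library labelled" applies to each direction given here. Without the library labelled knockdown 1 the difference was 0.83 ± 0.11 (SE), with an adjusted p of 0.00540 by limma. That library was singled out from these same data and has the knockdown value nearest the controls. Leaving it out therefore raises the difference and narrows the spread, and this p-value overstates the evidence.

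**Figure D1:**
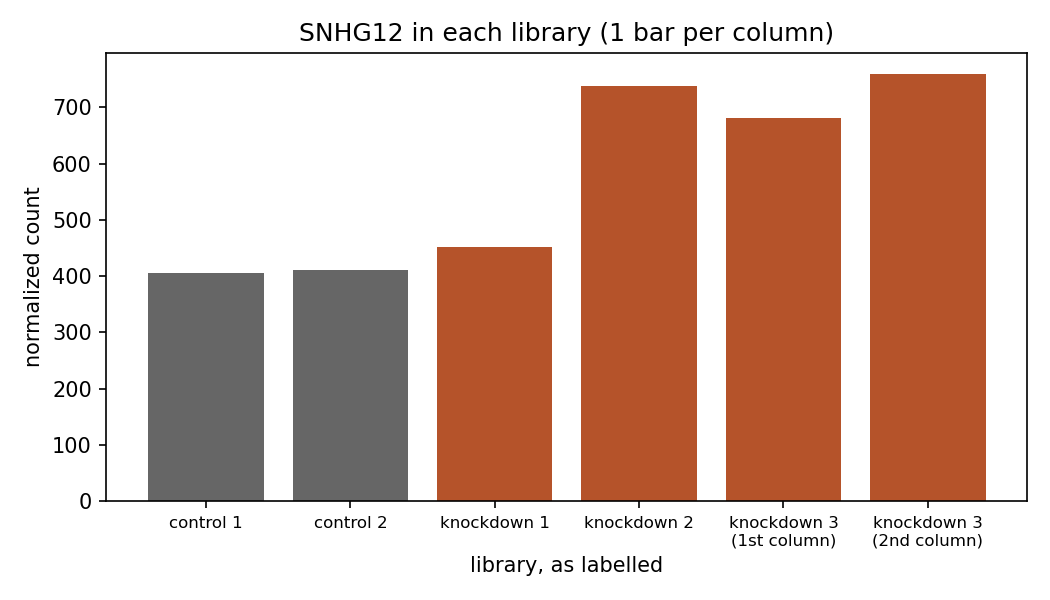
SNHG12 in each column of the table, as normalized count on the vertical axis, with 1 bar per column and no error bars. The libraries labelled control 1, control 2 and knockdown 1 lie at 406, 411 and 452, below the 681 to 759 of the remaining columns.

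The libraries did not fall into the labelled groups. Over 14149 genes, the library labelled knockdown 1 had a Pearson correlation of 0.994 with control 2 and 0.983 with control 1, where the controls had 0.981 with each other. Its correlation with the columns of knockdown 2 and 3 was 0.976 to 0.978, while those columns had at least 0.995 with one another. These correlations are across genes, which are not independent replicates. The first principal component held 73.5% of the variance and placed control 1, control 2 and knockdown 1 at -34.1, -19.3 and -23.0, opposite knockdown 2 at 24.1. The second held 15.8% and set control 1 (21.5) apart from control 2 (-14.8).

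**Figure D2:**
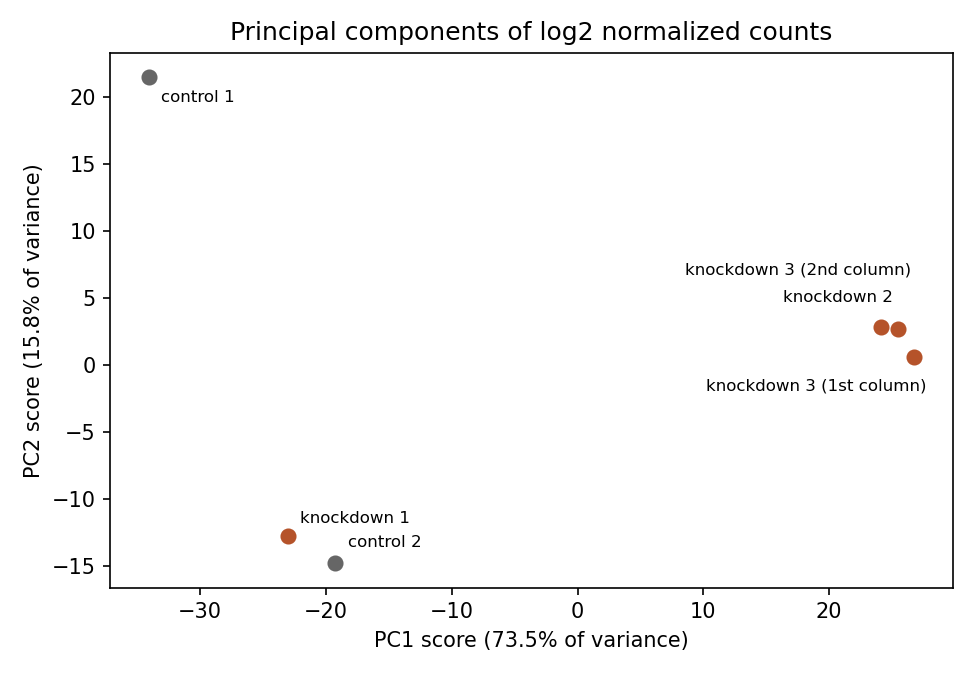
Scores of the 6 columns on the first and second principal components of log2 normalized counts (73.5% and 15.8% of variance), grey for control and brown for knockdown as labelled. Knockdown 1 lies beside control 2, and control 1 stands apart on the vertical axis.

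No gene passed the threshold between the groups as labelled. By limma 0 of 15656 genes passed, with 1239 at an unadjusted p under 0.05, and edgeR and DESeq2 on recovered reads also called 0 (1180 and 1448 unadjusted). None of the fixed lists held a called member, adjusted over the list alone or over all genes. The genes with the smallest p and higher values were SCARNA5 (log2 difference 0.82 ± 0.17 SE), TOP1, which encodes a DNA topoisomerase (0.66 ± 0.14), CREG2 (1.07 ± 0.25), MFSD6 (1.04 ± 0.26) and ANP32B (0.54 ± 0.14). Those with lower values were BOLA3-DT (-0.86 ± 0.21), SCRN2 (-0.66 ± 0.16), PIH1D1 (-0.55 ± 0.14), CST1 (-0.77 ± 0.20) and NUDT14 (-0.59 ± 0.15), each of these 10 with an adjusted p of 0.519 by limma. In each of the 10, knockdown 1 lay on the same side of both controls as knockdown 2 and 3. SCARNA5, for example, had 174 and 160 in the controls, against 315, 271 and 300 in knockdown 1, 2 and 3. Ranking by p over all knockdowns favours such genes.

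The count of called genes rests on the library labelled knockdown 1. Leaving it out, as was planned for every library in turn, gave 2870 of 15330 tested genes by limma, 1210 higher and 1660 lower. Leaving out any other library gave 0. The filter was reapplied without knockdown 1, so genes under 10 in both controls or in both remaining knockdowns were not tested. Since the library labelled knockdown 1 was recognised as different from these same values, the p-values of the fit without it do not count the choice and overstate the evidence. With each library at an equal total the split became 1898 higher and 1232 lower, with a shift of 0.11 in the median of all genes. The following genes with large differences in that fit were chosen after their values were seen. STC1, a secreted glycoprotein hormone, had 323 and 306 in the controls and 344 in knockdown 1, against 2393 in knockdown 2 and 2544 in knockdown 3. TNFAIP3, an inhibitor of NF-kB signalling, had 70.5, 42.0 and 60.7 against 430 and 424, and CDCP1 had 55.6, 89.6 and 63.3 against 1255 and 1253. In the other direction EXOC4, a subunit of the exocyst, had 3289, 2867 and 3028 against 513 and 483. LPP had 4607, 4030 and 4756 against 738 and 827, and ATF6, a sensor of endoplasmic reticulum stress, had 5363, 5427 and 5706 against 1098 and 1064. FAR2 had 4846, 4489 and 4743 against 1016 and 962. Other genes with large differences varied more among the controls and knockdown 1, such as PTHLH (13.6, 70.02 and 80.4 against 194 and 204), BCL2A1 (18.5, 48.5 and 42.8 against 178 and 210) and VTRNA1-3 (59.4, 85.9 and 130 against 328 and 402).

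At the level of lists, 6 of 39 passed camera at the preset correlation. With an estimated correlation 0 passed, and each of the 6 had an adjusted p = 0.869. Fry likewise called 0. The estimated correlation rests on 3 residual degrees of freedom, and fewer without knockdown 1, which leaves little power to call any list. Even senescence regulators, with an estimated correlation of -0.057, had 0.869. Its results here and below therefore do not decide whether a list differs. Endoplasmic reticulum chaperones were lower in 12 of 14 members, with a median log2 difference of -0.34 (camera adjusted p = 2.74e-04, limma), among them MANF (-0.40 ± 0.13 SE), PDIA4 (-0.51 ± 0.18) and HYOU1 (-0.44 ± 0.16). Basement membrane genes were lower in 11 of 12, with a median of -0.37 (0.00337), among them the collagen chains COL4A1 (-0.82 ± 0.35) and COL4A2 (-0.69 ± 0.27), LAMB1 (-0.56 ± 0.23) and NID2 (-0.82 ± 0.33). Endothelial identity genes were lower in 18 of 26, with a median of -0.20 (0.0288). VWF, the von Willebrand factor, differed by -0.87 ± 0.33 and the receptors TIE1 and TEK by -0.45 ± 0.18 and -0.42 ± 0.18, while SOX7 differed by 0.38 ± 0.16. None of these members passed singly. Naming members by the smallest p over all knockdowns favours those in which knockdown 1 moved too. MANF, for example, had 2869 and 2865 in the controls, against 2484, 1973 and 2078 in knockdown 1, 2 and 3. The list medians, by contrast, moved in knockdown 2 and 3. Relative to the controls the chaperone median was -0.01 in knockdown 1, -0.47 in knockdown 2 and -0.41 in the first column of knockdown 3. In the same order it was -0.01, -0.57 and -0.45 for basement membrane, and -0.0006, -0.23 and -0.24 for endothelial identity.

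Immediate early genes were higher in 13 of 14 members, with a median of 0.43 (camera adjusted p = 0.00337, limma), including DUSP1 (0.89 ± 0.45 SE), IER2 (0.37 ± 0.18) and KLF6 (0.30 ± 0.10). Cytosolic heat shock genes were higher in 9 of 12, with a median of 0.18 (0.0338), including HSPH1 (0.60 ± 0.21), HSP90AA1 (0.47 ± 0.16) and BAG3 (0.49 ± 0.18). Genes of the mitochondrial genome were higher in 13 of 13, with a median of 0.56 (6.46e-07), including MT-ND3 (1.04 ± 0.35), MT-ND1 (0.66 ± 0.21) and MT-CO3 (0.47 ± 0.14). The estimated correlation between the mitochondrial members was 0.961, against the preset 0.01. They moved nearly as 1 signal, so the p-value at the preset correlation overstates the evidence. For the remaining called lists the estimate ran from 0.146 (endothelial identity) to 0.473 (endoplasmic reticulum chaperones). These also lie above the preset value, so the p-values of those lists may overstate the evidence too. Relative to the controls, the immediate early median was 0.06 in knockdown 1, 0.57 in knockdown 2, and 0.54 and 0.48 in the columns of knockdown 3. In the same order the heat shock median was 0.06, 0.28, 0.17 and 0.27. Unlike the immediate early median, KLF6 was as high in knockdown 1 (3498) as in knockdown 2 and 3 (3463 and 3506), against 2905 and 2780 in the controls. The mitochondrial values moved with 1 control: mitochondrial mRNA made up 0.107% of the values in control 1 and 0.185% in control 2, against 0.212% to 0.219% in the knockdown columns. Without control 1 the mitochondrial median was 0.15 (0.00520), and without both control 1 and knockdown 1, a choice made after the data were seen, it was 0.13 and the call ended (0.0596). Without control 2 the calls for basement membrane (adjusted p = 0.197), endothelial identity (0.585) and heat shock (0.103) ended, and without control 1 those for immediate early genes (0.0620, median 0.24) and heat shock (0.180) did. The heat shock median was 0.180 without control 1, close to the 0.184 with all samples. Without knockdown 2, endothelial identity (0.0556) and heat shock (0.0512) ended. Endothelial identity also ended with quantile normalization (0.109) and the stricter filter (0.0539), and heat shock with camera on ranks (0.0521).

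**Figure D3:**
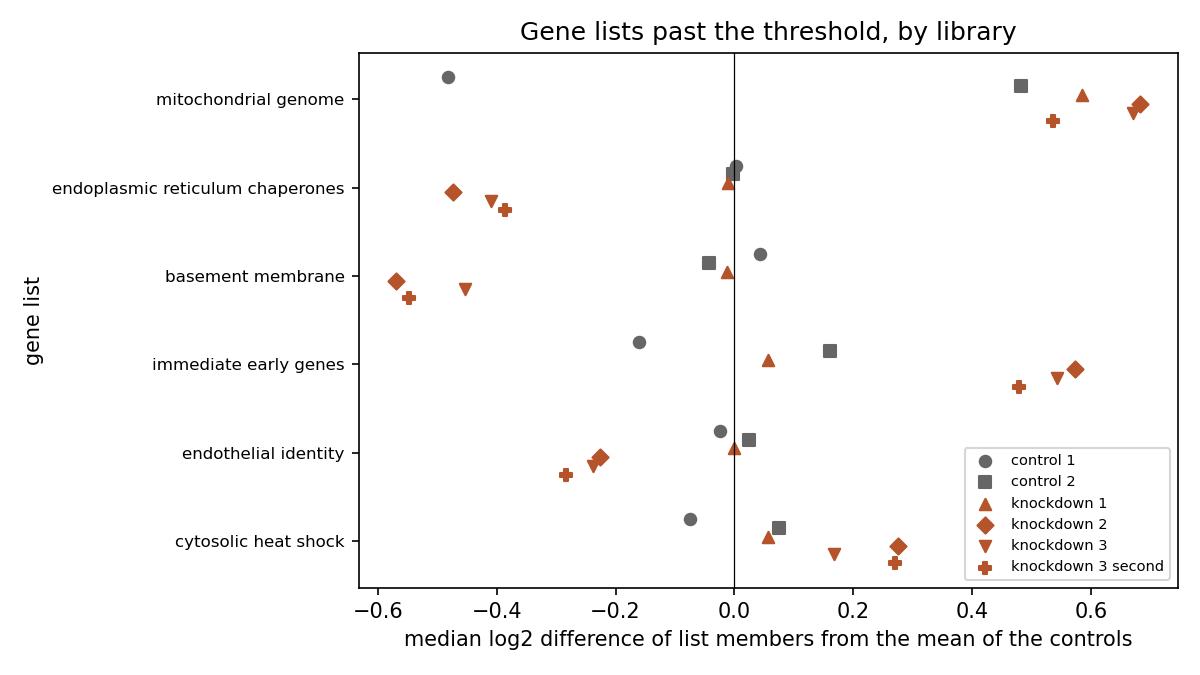
Median log2 difference of each list's members from the mean of the controls, 1 symbol per column, for the 6 lists past the threshold at the preset correlation. In basement membrane genes knockdown 1 lies at -0.01 and knockdown 2 at -0.57, and in mitochondrial genes control 1 lies at -0.48 and control 2 at 0.48.

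Lists on DNA damage and repair did not pass with all 5 samples. Of 25 p53 target genes 16 were higher and 9 lower (camera adjusted p = 0.252, limma). The higher included POLH (0.62 ± 0.23 SE), FAS (0.71 ± 0.30) and BBC3 (0.49 ± 0.24). SPATA18, a member chosen after its values were seen, differed by -1.48 ± 0.72. Without knockdown 1 the p53 targets passed at the preset correlation (0.0428, with 11 members called higher and 2 lower), and had an adjusted p = 0.494 with an estimated correlation. In non-homologous end joining 7 of 12 were higher (0.599). PRKDC, the catalytic subunit of DNA-dependent protein kinase, differed by 0.58 ± 0.25 and XRCC6 by -0.14 ± 0.10. PRKDC had 12792 and 11210 in the controls, 12428 in knockdown 1, 20577 in knockdown 2 and 22496 in knockdown 3. Homologous recombination (7 of 19 higher, 0.660) included RAD50 (0.46 ± 0.17). Base excision and single-strand break repair (11 of 18 higher, 0.999) included FEN1 (-0.32 ± 0.13) and NTHL1 (-0.39 ± 0.15), and the DNA damage checkpoint (7 of 18 higher, 0.816) included CHEK1 (-0.25 ± 0.14).

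Lists on oxidative stress, senescence and inflammation did not pass with all 5 samples either. NRF2 target genes were lower in 11 of 17 members (camera adjusted p = 0.252, limma), with TXNRD1 at -1.22 ± 0.50 (SE), PIR at -0.89 ± 0.38 and SQSTM1 at -0.25 ± 0.10. Antioxidant enzymes (10 of 17 lower, 0.592) included PRDX5 (-0.29 ± 0.10) and PRDX2 (-0.29 ± 0.11), and metallothioneins (3 of 6 higher, 0.993) included MT2A (0.51 ± 0.24). Senescence regulators (8 of 13 lower, 0.517) included GLB1 (-0.52 ± 0.21). Senescence-associated secretory factors (12 of 20 higher, 0.816) included CCL2 (-0.89 ± 0.35) and TIMP1 (0.60 ± 0.24). NF-kB targets (9 of 15 higher, 0.520) included NFKB1 (0.45 ± 0.21), and interferon-stimulated genes (11 of 20 lower, 0.572) included IFI27 (-0.86 ± 0.27) and OAS3 (0.56 ± 0.24). ATF4 targets were higher in 11 of 16 (0.0909), with TRIB3 at 0.93 ± 0.37, ASNS at 0.55 ± 0.26, ATF4 at 0.36 ± 0.17 and SLC7A11 at -0.35 ± 0.18. Without knockdown 1, ATF4 targets (0.00171, median 0.54, 10 members called higher and 1 lower) and NRF2 targets (0.0432, 8 called lower and 2 higher) passed at the preset correlation, each with an adjusted p = 0.494 with an estimated correlation. Apoptosis effectors (9 of 15 lower, 0.816) included BCL2L11 (-0.94 ± 0.37).

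Among the genes around SNHG12, 9 were measured and 6 were lower (camera adjusted p = 0.660, limma), with TAF12 at -0.38 ± 0.14 (SE) and GMEB1 at 0.39 ± 0.21. Other snoRNA host genes were higher in 9 of 13 (0.520), with SNHG6 at 0.77 ± 0.34, SNHG1 at 0.69 ± 0.35, SNHG16 at 0.33 ± 0.16 and EPB41L4A-AS1 at -0.38 ± 0.18. Without knockdown 1 the host genes passed at the preset correlation (0.0400), with an adjusted p = 0.494 with an estimated correlation. Of 5 listed snoRNAs of SNHG12, 2 were measured at low values, SNORD99 (-0.67 ± 0.53) and SNORA66 (-0.35 ± 0.54), and SNORA66 is annotated outside SNHG12. Too few members were measured for a test of that list.

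Markers of other cell types were few. Erythroid markers had 0 of 9 in the table, leukocyte markers 2 of 15, with LAPTM5 at 0.13 ± 0.11 (SE), and epithelial markers 2 of 9, with EPCAM at -0.19 ± 0.37 and ESRP2 at 1.07 ± 0.41. Fibroblast markers (5 of 10, camera adjusted p = 0.517, limma) included PRRX1 (1.24 ± 0.55), COL3A1 (-0.54 ± 0.31) and FAP (-0.46 ± 0.40). Smooth muscle and pericyte markers (4 of 10, 0.803) included NOTCH3 (0.92 ± 0.64), MYH11 (0.43 ± 0.39) and RGS5 (-0.08 ± 0.15). Lymphatic endothelial markers (4 of 6, 0.993) went both ways, with RELN at 0.42 ± 0.24 and PROX1 at 0.27 ± 0.20 and with FLT4 at -0.49 ± 0.28 and LYVE1 at -0.49 ± 0.29. Without knockdown 1, limma called ESRP2 (1.38, adjusted p = 0.0337) higher and FLT4 (-0.78, 0.0113), LYVE1 (-0.76, 0.0318) and FAP (-0.85, 0.0443) lower.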

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

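Tests with the columns headed 6 taken singly, with GC correction, and combined with knockdown 1 left out were chosen after the data were seen. Genes past the threshold stayed at 0 under the other pseudocounts, filters, scalings and count models on all 5 samples, and array weights gave 2427 (1064 higher, 1363 lower). Array weights are estimated from these same values, and 2163 of the 2427 genes were also called without knockdown 1. Results with array weights are therefore not separate evidence. Leaving out 1 library gave 0 to 2870 genes (0 to 1210 higher, 0 to 1660 lower), 3 to 15 lists, and 0.48 to 0.83 for SNHG12, the upper ends without knockdown 1. With knockdown 1 left out, genes (higher, lower) numbered 3012 (1265, 1747) by edgeR, 3214 (1380, 1834) by DESeq2, 2883 (1215, 1668) with TMM, 3085 (1481, 1604) with quantile normalization, 3130 (1898, 1232) at equal totals, 2872 (1087, 1785) with GC correction, and 2734 (1148, 1586) and 2848 (1189, 1659) with the first or the second column headed 6. Without both control 1 and knockdown 1 there were 6342 (3071, 3271), with the lone control assumed to vary like the knockdowns. In the same order SNHG12 was 0.84, 0.84, 0.84, 0.84, 0.93, 0.74, 0.79, 0.87 and, without both, 0.83, and 0.82 with array weights, each past the threshold. Lists past the threshold numbered 15 with TMM, 11 with quantile normalization, 14 at equal totals, 15 with GC correction, 12 and 15 with single columns, 15 without both, 10 with array weights, 5 with the stricter filter, quantile normalization on all 5 samples or camera on ranks, and 0 with an estimated correlation or fry. Directions of genes that did not pass were reversed for XRCC6 (0.033, quantile normalization with knockdown 1 left out), RGS5 (0.065, quantile normalization), NOTCH3 (-0.18 without control 1 and knockdown 1, and -0.0045 to 1.84 leaving out 1 library), MALAT1 (0.075 with quantile normalization, 0.049 at equal totals, 0.052 with the replicate block, and -0.15 to 0.052 leaving out 1 library) and EPCAM (0.41 without control 1 and knockdown 1, 0.038 at equal totals with knockdown 1 left out, and -0.65 to 0.28 leaving out 1 library). The cause was not tested.

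The replicate block used only the numbers 1 and 2, gave 0 genes, 680 at an unadjusted p under 0.05, 7 lists, and 0.50 for SNHG12. Deviations of same-numbered samples had correlations of 0.136 and 0.0873 over genes. Control 2 with knockdown 3, which differ in number, had a higher one (0.156). With 2 controls, each value returns with the opposite sign for the other control, so the signs are partly forced. These values do not show a pairing, and the samples share only a number. Leaving out control 3 was not run. The lowest sum of reads of a gene over the 6 columns was 61, and counting error is largest for such genes.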

Other observations

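Of the tests here, those of an exchange of labels, of a wrong heading, of depth, of library complexity and of gene length were chosen after the result was seen. Lists not yet described did not pass camera with all 5 samples. Histone genes were lower in 11 of 15 members (adjusted p = 0.210, limma), with H2BC8 at -0.46 ± 0.18 (SE). Mitosis genes were lower in 15 of 20 (0.307), with BUB1B at -0.33 ± 0.19, and DNA replication genes were higher in 12 of 20 (0.816), with TYMS at 0.46 ± 0.12. Endothelial junction genes were lower in 9 of 14 (0.243), with CTNND1, which encodes p120 catenin, at -1.06 ± 0.42 and CDH5 at -0.40 ± 0.20. Genes of endothelial-to-mesenchymal transition were lower in 11 of 15 (0.179), with CDH2 at -0.48 ± 0.21, and Notch pathway genes were higher in 7 of 12 (0.877), with HEY1 at 0.69 ± 0.25. Without knockdown 1, histone genes (0.00740), mitosis genes (0.00790) and endothelial junction genes (0.0440) passed at the preset correlation, with an adjusted p = 0.494, 0.549 and 0.494 with an estimated correlation.

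Lipoprotein uptake genes were lower in 7 of 9 members (camera adjusted p = 0.170, limma), with ACVRL1 at -0.47 ± 0.19 (SE). Cholesterol synthesis genes were higher in 9 of 17 (0.831), with LSS at -0.35 ± 0.14. This list's median was 0.02 and its mean -0.02. Glycolysis genes were lower in 9 of 15 (0.520), with PFKL at -0.41 ± 0.12 and HK2 at 0.60 ± 0.24, and hypoxia genes were higher in 7 of 12 (0.999), with DDIT4 at -0.40 ± 0.18. Autophagy and lysosome genes were lower in 11 of 16 (0.182), with CTSB at -0.48 ± 0.19 and MAP1LC3B at 0.36 ± 0.11. Nuclear-encoded respiratory chain genes were lower in 13 of 20 (0.252), with COX6C at -0.52 ± 0.25, and ribosomal protein genes in 22 of 30 (0.0614), with RPS9 at -0.42 ± 0.17. Abundant nuclear RNAs were higher in 2 of 4 (0.519), with NEAT1 at 0.35 ± 0.19 and MALAT1 at -0.02 ± 0.15. Without knockdown 1, lipoprotein uptake (0.0267) and autophagy and lysosome genes (0.0440) passed at the preset correlation, each with an adjusted p = 0.494 with an estimated correlation.

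The library labelled knockdown 1 lies with the controls. For a partial response or a mixture, a slope between 0.25 and 0.75 along the axis from the controls to knockdown 2 and 3 was predicted. The slopes of knockdown 1 were -0.0532 and 0.0185, where knockdown 2 set against knockdown 3 gave 0.448 and 0.850 in the same pairings of the controls. Since 0.448 lies within the bounds, they do not part a partial from a full response. Both slopes of knockdown 1 lie below the bounds and below those of knockdown 2, where a weak response could also fall. An exchange with control 1 or control 2 needs a control out of place, and the controls correlated more closely with each other than with knockdown 2 or 3, by a margin of only 0.00115, while chi-square per gene was 27.1 between the controls and at least 57.6 between a control and those columns. The correlation of knockdown 1 with control 2 exceeded that of the controls by 0.0134. A wrong heading on the column of knockdown 1 and a culture that did not respond cannot therefore be told apart here. The headings have a fault in any case, since 6 heads 2 columns and 3 heads 0, which leaves control 3 without a column. If 1 of the columns headed 6 were control 3, a control would lie with knockdown 2 on the first component. The scores were 26.8 and 25.5 for these columns and 24.1 for knockdown 2. That control would also have been averaged into knockdown 3. An exchange with control 3 or of all labels between the groups was not tested, and in the table's order of headings (1, 5, 2, 6, 4 and 6) libraries on the negative and the positive side of the first component alternate, with the column headed 4, read as knockdown 1, on the negative side.

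SNHG12 is higher in the libraries labelled knockdown 2 and 3 than in the controls. The difference did not depend on the choice among the scalings tried, since the lowest log2 difference over 3 other scalings was 0.836. These scalings moved the median of all genes little, from 0.01 as deposited to 0.11 at equal totals. A fall of SNHG12 under the bound of 0.2 was therefore unlikely from the start, and the test says little about scaling beyond them. Overlapping genes share 9.54% of its exonic bases, between the bounds of 5% and 20% set beforehand. These 407 bases lie in the small same-strand RNAs SNORA16A, SNORA44 and SNORA61 apart from 8 shared with TRNAU1AP on the other strand. The exons of all annotated transcripts of SNHG12 were merged into 2 for this share, so it is not that of a single spliced transcript. The median of 13 other snoRNA host genes was 0.280 (quartiles -0.003 and 0.486), between 0.2 and 0.4. Reads of overlapping genes and a rise shared with host genes therefore stay open, as do peroxide, an effect of the gapmer and wrong labels, which were not tested.

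The library labelled control 1 stands apart from control 2 and knockdown 1. It lists 221 genes at 0, where a column of knockdown 3 with fewer reads (25168013 against 25424726) lists 0, which argues against depth. GC content is argued against as the main source by a Spearman's rho of 0.0585 across genes (0.396 for control 2 minus knockdown 1), and the SD of the difference over genes was 0.469 before and 0.462 after loess correction, which also removes the curved trend seen in medians of -0.27 at 65% to 70% GC and 0.09 at 50% to 55%. Poisson counting allowed 0.169 genes at 0 in control 1, so the listed number is 1306 times that. The rule for low complexity asked that no other library exceed 5 times its allowance. The other allowances were 0.00441 to 0.0794 genes, so 1 gene at 0 was enough to break it. Control 2 with 5 genes (519 times) did so, as did knockdown 1 with 2. This test could hardly decide, and low complexity cannot be told apart from spread between libraries by it. The counts themselves were 221 in control 1 and 0 to 5 in the other columns.

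A hypothesis prompted by long genes such as EXOC4 and LPP among the largest differences is that genes lower in knockdown 2 and 3 tend to be long. Without knockdown 1, rho between genomic length and the log2 difference was -0.180 across genes, and -0.123 after GC correction. Called lower genes had a median length of 63.5 kb against 26.3 kb for called higher genes, and 33.0% of 512 genes over 300 kb were called lower against 4.83% of 4038 genes under 10 kb. The comparison of knockdown 1 with control 2 gave a rho of 0.178, of nearly equal size and opposite sign, and 0.0608 after GC correction. Length may therefore track library preparation as well as treatment, and the weight given to that pair was decided after its value was seen.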
